A study of Caenorhabditis elegans with 2 samples.

How the data were processed

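ChIP-seq peak lists were used from 2 biological replicates of 1 group, hermaphrodite late embryos of C. elegans with a GFP-FLAG tag on SDC-2, immunoprecipitated with an anti-GFP antibody after sonication, per the labels. There were 8 lists, 4 kinds on each of 2 genome builds (ce10 and ce11). Per the deposited README texts, the authors called a list of peaks and background on each replicate and on both replicates pooled, each against a control alignment, and derived the IDR list from these 3 lists. The same control alignment served both replicates and the pooled call, per those texts. The peak caller, the aligner and the IDR threshold are not given in the sources used here. The control reads, and ChIP of an untagged strain, were not analysed here.

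Each list holds a signal per peak, a value that the authors' peak caller gave and that was deposited with the peak. It is used here within a list, to describe, rank and filter peaks and to compare X with autosomal IDR peaks, and values in the pooled list and in the replicate lists are on separate scales and are not set against each other. The deposited −log10 q-value of the authors' peak caller takes a maximum of 2.66 that 1149 of the IDR peaks share, so it does not rank them and was not used further. The p-value column holds no values. The 1344 IDR peaks are the 1344 strongest peaks of the pooled list by signal. The lists give no read counts, so the depth is unknown, and intervals are exact (Clopper-Pearson, 95%) for the number of peaks counted.

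The analyses use the ce11 lists, the build of the reference genome (WBcel235) and of the Ensembl release 115 annotation. No ce11 peak ran past a chromosome end. The ce10 lists were counted without any annotation. Peaks on the mitochondrial genome, 1 in the IDR list, were left out of the comparisons. Positions are given from 1.

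Shares of peaks on X were tested against the X share of the nuclear sequence with two-sided exact binomial tests. Peaks of both replicates were matched where summits lay within 100 bp, among as many of the strongest peaks as there were IDR peaks. Medians of signal were compared with a two-sided permutation test of 100000 resamples. Summits were set against annotated transcript 5′ ends within 1000 bp and against coding exons, untranslated exons, introns and intergenic sequence of protein-coding genes, in this order of priority. The MEX consensus was sought on both strands within 100 bp of the summit, with at most 2 mismatches. All 8-mers found in at least 10 windows were tested with Fisher exact tests, reverse complements merged, against windows 2000 bp to either side. Gene lists were tested with exact hypergeometric distributions stratified by X and autosomes, with all protein-coding genes as background, or all tRNA, snRNA, snoRNA, miRNA and rRNA genes for the lists of small RNA genes. Spacing on X was compared with 10000 draws from the X summits of the pooled list. Adjusted p-values follow Benjamini and Hochberg. Since counts are of peaks and genes in 2 libraries, p-values do not measure the spread between worms.

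The peaks and genes named in the report follow a rule fixed before the data were examined: the nearest protein-coding 5′ end of the 15 strongest X and 10 strongest autosomal IDR peaks, her-1, xol-1 and sdc-2 whatever their values, and up to 4 members per gene list with the highest signal within 1000 bp, of which some are given. For the test on copies of the transgene, 2 rules by which its region would be too small to decide were written after the result and are not used. By the first, 113 peaks of median width fit end to end where 106 are needed, so the test stands, and by the second, the densest region of that size in the pooled list holds 42, so it would not. The verdict of the test was computed from the lower bound of the excess of X peaks against these 113, a comparison also written after the result. What is said of the region in the report rests on the 0 IDR peaks found there, which also meet the bound written before the result. Copies of the locus give no peaks outside it. For the background of the peak caller, a later rule that left the test undecided was dropped too, and the explanation was narrowed to a background alike at all signal levels. Tests, gene lists and alternatives were fixed at the same point, except where a comparison is said to have been chosen later. The alternatives were other expected shares, single replicates, the upper part of the IDR list, the ce10 lists, other distances, overlaps and mismatch limits, and other backgrounds. Other backgrounds for the small RNA genes were added after the result was seen.

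The tests were checked on simulated data. Of 200 8-mers planted in 40 each of 563 windows drawn from X, 99.5% were found among 10663 8-mers tested, and 0 were called without planting. MEX planted in 57 of 563 windows gave 58 windows with a match, where 1 had a match by chance. All these windows were random X windows, so the checks do not cover the higher GC of windows at summits. False calls from composition were therefore not simulated, and the planted MEX copies were exact. Counts drawn for random gene lists passed an exact p of 0.05 in 2.25% of 2000 draws. They were drawn from the distributions that the test assumes, so a rate no higher than 0.05 was fixed in advance. Genes that share a summit were not simulated. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.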

Results

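SDC-2 is the hermaphrodite protein that brings the dosage compensation complex of C. elegans to both X chromosomes, where the complex lowers transcription. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with an anti-GFP antibody in worms of strain OP92, which carry SDC-2 with a GFP-FLAG tag at its C terminus. The chromatin came from hermaphrodite late embryos 3.25 hours after synchronization by egg bleaching, in 1 group of 2 biological replicates. The replicate lists of peaks and background held 25174 peaks (replicate 1) and 24450 peaks (replicate 2), and the list called on the pooled alignments held 26640. The list that passed the authors' threshold of irreproducible discovery rate (IDR) held 1344 peaks, of which 1343 lay on the 6 nuclear chromosomes and are called IDR peaks here. Their median width was 450 bp, and the authors' signal ran from 82.4 to 21888 with a median of 111.8. The peak lists give no read counts, so the depth of the libraries is unknown, and the intervals given cover the counting of peaks only.

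The comparison that the target implies is X against the autosomes. X held 563 of the 1343 IDR peaks, 41.9% (exact 95% interval 39.3 to 44.6%), on 17.7% of the nuclear sequence and with 13.7% of the protein-coding genes. That is 31.8 peaks per Mb on X and 9.45 per Mb on the autosomes, a ratio of 3.36 (two-sided exact binomial p = 3.37e-95). Among the 780 autosomal IDR peaks, chromosome III held 24.4% on 16.7% of the autosomal length (adjusted p = 2.50e-07), while chromosome V held 17.6% on 25.3% (adjusted p = 6.15e-07) and chromosome IV 17.3% on 21.2% (adjusted p = 0.0125), by exact binomial tests over the 5 autosomes. Chromosomes I and II did not pass this exact test (adjusted p = 0.179 and 0.160). The peaks, not the worms, are counted in these tests, so the p-values describe these 2 libraries.

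The share of X was highest among the strongest peaks. All of the 20 strongest peaks of the pooled list lay on X, as did 49 of the 50 strongest, 88 of the 100 strongest and 149 of the 200 strongest (74.5%, interval 67.9 to 80.4%). The share was 49.3% at ranks 201 to 500, 31.8% at ranks 501 to 1000 and 31.2% at ranks 1001 to 1343. Below the IDR threshold X held 23.9% of ranks 1344 to 4000 and 19.6% of the peaks from rank 16001 on, close to its 17.7% of the sequence. The replicates gave the same course separately, with 89 X peaks among the 100 strongest in replicate 1 and 87 in replicate 2.

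**Figure D1:**
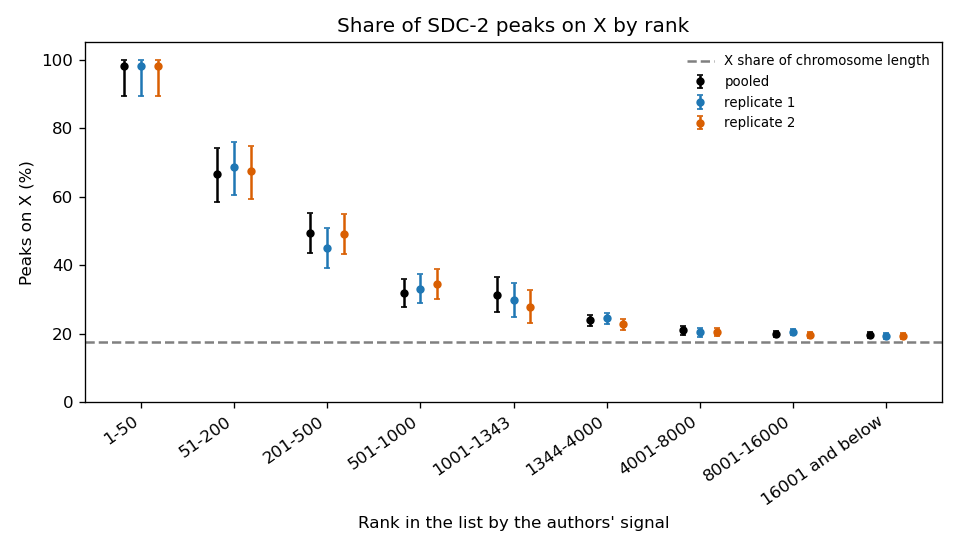
The share of peaks on X (%, with exact 95% binomial intervals) is plotted against the rank of the peaks by the authors' signal in the pooled list and in each replicate list, with the X share of the chromosome length as a dashed line. In all 3 lists the share falls from 98% at ranks 1 to 50 to under 20% from rank 16001 on.

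X peaks also had the higher signal. The median was 135 on X (quartiles 99.4 to 231) and 104 on autosomes (quartiles 91.6 to 131), a ratio of 1.30 (difference of medians 30.8, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The strongest X peak reached 21888 and the strongest autosomal peak 1646, a 13.3-fold difference, and 36 X peaks lay above every autosomal one. A signal over 1000 was seen at 41 X peaks and at 1 autosomal peak. The 20 strongest X peaks held 63.9% of the summed signal of all X IDR peaks, and the 50 strongest held 79.8%.

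**Figure D2:**
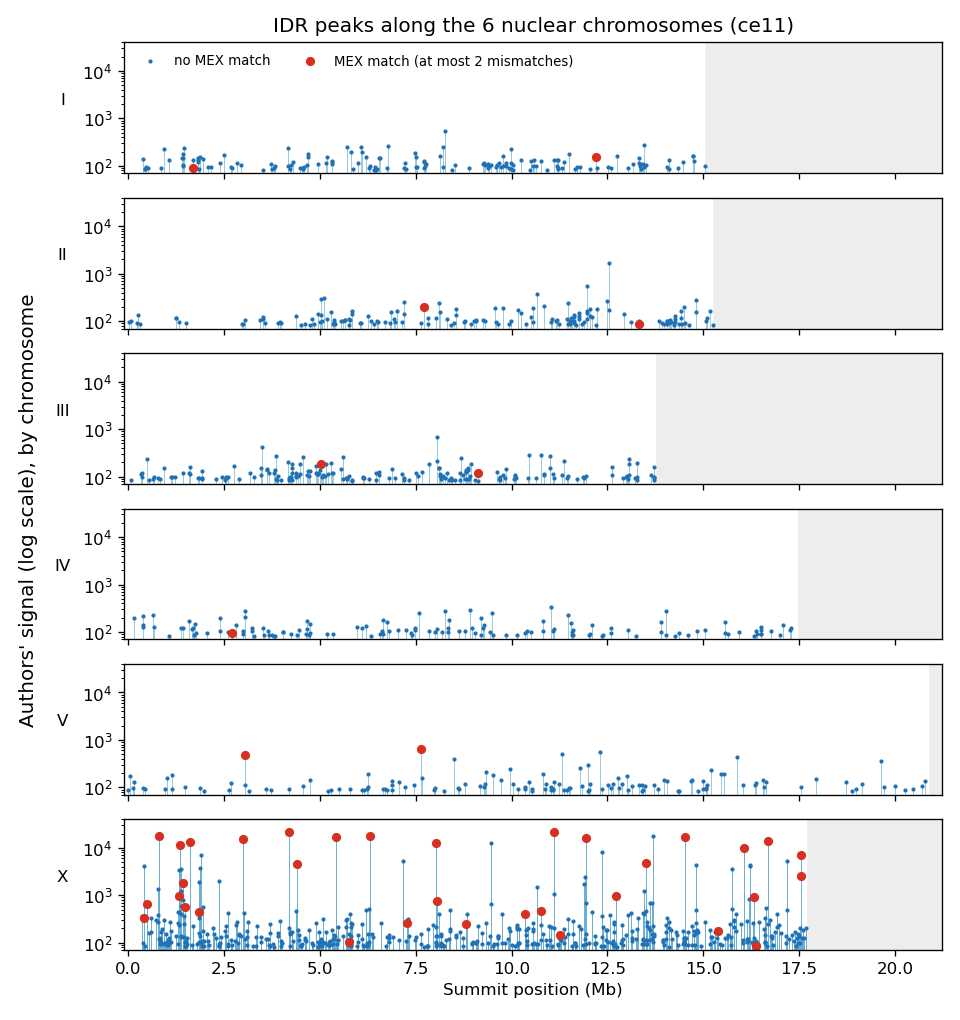
The authors' signal of each nuclear IDR peak (log scale) is plotted against its summit position (Mb, ce11) on the 6 chromosomes, with red points for summits that have a MEX match of at most 2 mismatches within 100 bp and grey areas past the chromosome ends. The X chromosome carries 41 peaks over a signal of 1000 and the autosomes 1, on chromosome II.

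The strongest X peak lay at X:11093690-11094738, in intergenic sequence 3971 bp downstream of the nearest protein-coding 5′ end, that of W02H3.3, with a signal of 21888 in the pooled call, 10811 in replicate 1 and 11127 in replicate 2. The next was at X:4208518-4209782, 1788 bp upstream of F20B6.9 (21188), followed by an intergenic peak at X:13700397-13701345, 6048 bp upstream of K02D3.1 (17776). The fourth, at X:6296042-6297050, was in an intron of mom-1, which encodes a protein needed for Wnt secretion, and 3380 bp upstream of cest-16 (17635). The fifth was intergenic near gtr-1 (17621), and nspc-17 had a peak 741 bp upstream (16994). The seventh, at X:5429040-5430079, was the only one of these 15 in coding sequence, in an exon of the polyketide synthase gene pks-1, with C41A3.2 as the nearest 5′ end (16766). Peaks near F55G7.5 (16064), F22H10.2 (14126), fbxb-58 (13174), ZK899.6 (12626) and T27A8.7 (9721) were intergenic. The peak near Y41G9A.17 (15698) was in an intron of that gene, and ins-39, an insulin-like peptide gene, had its peak 628 bp upstream (11464). The 15 strongest peaks held ranks 1 to 15 in both replicates.

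The gene xol-1, the switch that sets male against hermaphrodite development and that keeps sdc-2 off in males, had the X peak of rank 12 at X:8035925-8037042, 4884 bp upstream of its 5′ end (12899; 6242 in replicate 1 and 6686 in replicate 2). The summit of this peak lay closer to a tRNA gene, 328 bp from its 5′ end. A weaker IDR peak had its summit 157 bp from the xol-1 5′ end, with a signal of 216 and rank 209. At her-1, the male-promoting gene on chromosome V (V:9697015-9702035) that is the known autosomal target of SDC-2, no IDR peak was found in the gene or within 1000 bp. The nearest IDR summit was 30491 bp from the closest annotated her-1 transcript 5′ end, which lies inside these coordinates. The best of 3 peaks at her-1 in the pooled list had rank 10706 and a signal of 36.0. Its rank was 6301 in replicate 1 and 11398 in replicate 2. The sdc-2 gene itself (X:11522707-11533450) had no peak in the pooled list and its nearest IDR summit 41126 bp from its 5′ end.

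The strongest autosomal peak was at II:12550902-12551393, in intergenic sequence 3293 bp downstream of the 5′ end of F49C5.16, with a signal of 1646, 822 in replicate 1 and 824 in replicate 2. The next lay 532 bp upstream of K12H4.5 on chromosome III (675) and near str-47, a chemoreceptor gene on chromosome V (631). Peaks followed in an intron of frm-7 near F55C5.17 (559), near W03C9.1 (554), upstream of sre-23 (533), in an intron of cutl-18 (495), upstream of chpf-2 (471), near str-56 (426) and upstream of M01F1.9 (412). All 10 held ranks from 37 to 95 in each replicate list. The rule names protein-coding genes only, and other genes can lie closer. The summits near F55C5.17 and W03C9.1 lay 33 and 102 bp from the 5′ ends of the snoRNA genes C51F7.4 and W03C9.9. No IDR peak lay within 20000 bp of sdc-2 or of unc-119, the rescue marker common in such strains, where the density of their chromosomes would give 1.61 and 0.638 peaks, but the region of sdc-2 held only 1 peak of the pooled list.

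The replicates shared their strong sites. Among the 50 strongest peaks of each replicate, 48 had summits within 100 bp of each other, and among the 200 strongest 173 did (86.5%). Among the 1343 strongest it was 829, 61.7% (interval 59.1 to 64.3%). X peaks of replicate 1 were found again more often than its autosomal peaks, 402 of 554 (72.6%) against 427 of 789 (54.1%, two-sided Fisher exact p = 6.49e-12). X peaks were also stronger, so rank is mixed into this difference, and among the 200 strongest it did not pass, with 134 of 152 on X (88.2%) and 39 of 48 on autosomes (81.25%, Fisher exact p = 0.231; p = 0.0553 for peaks of replicate 2 sought in replicate 1). In the full replicate lists, 1286 of the 1343 IDR peaks had a summit in both. The IDR list was derived from these lists, which share a control alignment, so a high number was partly fixed in advance.

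Autosomal IDR summits lay near gene starts more often than X summits, as autosomal bases do. Within 1000 bp of a protein-coding 5′ end lay 297 of 563 X summits, 52.8% (interval 48.5 to 56.9%), and 484 of 780 autosomal summits, 62.1% (interval 58.5 to 65.5%; Fisher exact p = 7.64e-04, adjusted p = 0.00137 over 25 tests of position). Of all bases, 34.9% on X and 42.6% on autosomes lay that close, so summits exceeded the bases 1.51 times on X and 1.46 times on autosomes. By the same exact test, intergenic sequence held 76.4% of X summits and 62.8% of autosomal summits (adjusted p = 3.48e-07), introns 18.3% and 28.3% (adjusted p = 4.44e-05) and coding exons 2.49% and 5.90% (adjusted p = 0.00494). Intergenic bases made up 44.5% of X and 35.8% of the autosomes, so the excess of summits there was about the same (1.72 and 1.75 times). Relative to their bases, 30.6% and 33.7% for introns and 19.97% and 25.6% for coding exons, summits were fewer on X (0.597 and 0.125 times) than on autosomes (0.841 and 0.230 times). The 50 strongest X peaks, a number chosen after the lists were seen, stood apart: 8 of them (16%, interval 7.17 to 29.1%) lay near a 5′ end, against 56.3% of the other X peaks (Fisher exact test, adjusted p = 9.60e-08). Without these 50, the difference between X and autosomes was 56.3% against 62.1% and did not pass (exact test, adjusted p = 0.0591). Counted by gene, 305 of 2731 protein-coding genes on X (11.2%) and 621 of 17242 on autosomes (3.60%) had an IDR summit within 1000 bp of a 5′ end (Fisher exact p = 1.90e-53).

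The 12 bp MEX motif TCGCGCAGGGAG, known from the recruitment elements on X that bring in the dosage compensation complex, was concentrated in the strongest X peaks. A match with at most 2 mismatches lay within 100 bp of 14 of the 20 strongest X summits (70%, interval 45.7 to 88.1%), 8 of the next 30, 6 of 50 at X ranks 51 to 100, 3 of 100 at X ranks 101 to 200 and 3 of the remaining 363. Over all X IDR peaks it was 34 of 563 (6.04%), against 9 of 780 autosomal peaks (1.15%; odds ratio 5.51, two-sided Fisher exact p = 7.66e-07) and 3 of 1126 windows 2000 bp away from the X summits (0.266%; p = 7.72e-14). The 9 autosomal matches were also above the 2 of 1560 windows beside the autosomal summits (Fisher exact p = 0.00134). The peaks near W02H3.3 and Y41G9A.17 had the exact consensus. Within 100 bp of the summit of rank 3, near K02D3.1, no match was closer than 5 mismatches. The rest of that peak, which is 949 bp wide, was not searched. With at most 3 mismatches the share was 19.5% on X and 16.7% on autosomes, and the difference did not pass (Fisher exact p = 0.194). Beside the autosomal summits it was 63 of 1560 windows (4.04%, Fisher exact p = 6.24e-24), and autosomal windows matched on GC, a comparison chosen after the result was seen, had a median of 9.86% over 100 draws.

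**Figure D3:**
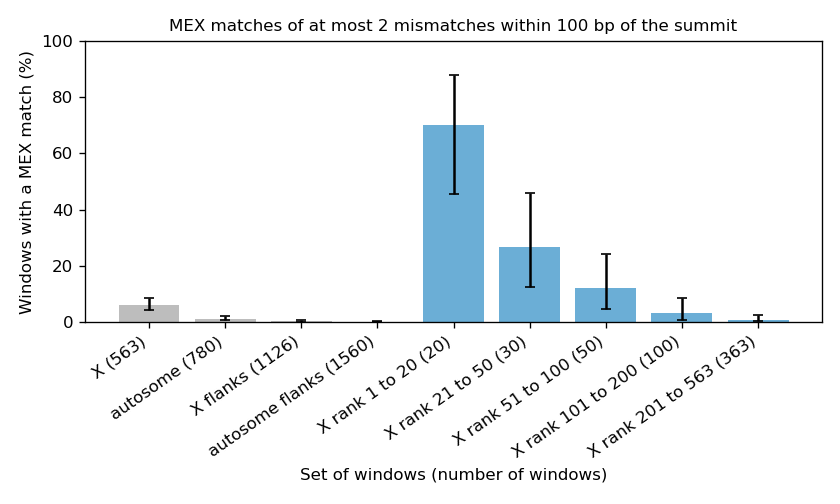
The share of windows with a MEX match of at most 2 mismatches (%, bars from 0, exact 95% binomial intervals) is drawn for X and autosomal IDR peaks, for windows 2000 bp to either side (grey) and for X peaks by their rank on X (blue), with the number of windows in brackets. The share is 70% at X ranks 1 to 20 and 0.826% at X ranks 201 to 563.

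Read from the genome, near-exact MEX sequences lay at IDR summits more often on X than on autosomes. Of 32 sequences on X with at most 1 mismatch to MEX, 22 (68.8%, interval 49.99 to 83.9%) lay within 100 bp of an IDR summit, against 1 of 37 on autosomes (2.70%, interval 0.0684 to 14.2%; two-sided Fisher exact p = 2.01e-09). Of the X summit windows, 18 held such a sequence, so sequences that share a summit may be counted separately, while the test treats them as independent. The autosomal sequence was the one at the peak upstream of chpf-2 on chromosome V (V:3040972-3041314). Such sequences were 4.03 times as dense on X as on autosomes (binomial p = 3.80e-08). The exact consensus occurred 3 times on X and 0 times on autosomes, and the X copy outside the 100 bp limit lay 210 bp from the summit of rank 9 near Y41G9A.17. X sequences with 1 mismatch also lay inside the IDR peaks of rank 36 and 16, but 107 and 430 bp from their summits. Of the others not counted, 1 each lay 52 and 86 bp from pooled summits of rank 1466 and 7121. The rest lay 664 to 4231 bp from any pooled summit. The 68.8% therefore depends on the 100 bp limit and on the IDR threshold. Sequences with 2 mismatches were about as dense on X (14.2 per Mb) as on autosomes (16.1 per Mb; binomial p = 0.0802), yet 25 of 252 on X and 8 of 1325 on autosomes lay at an IDR summit (Fisher exact p = 1.79e-14). This count over the genome was chosen after the peak lists were seen.

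A search of all 8-mers found the same leading sequences on X and on autosomes. AGACGCAG lay within 100 bp of 69 of 563 X summits (12.3%) and in 3 of 1126 windows 2000 bp away (exact test, adjusted p = 2.82e-26), and in 95 of 780 autosomal windows (12.2%) against 16 of 1560 (adjusted p = 3.40e-27). GAGACGCA was in 68 X windows and 96 autosomal windows, and GAGAGAGA in 62 and 99. By Fisher exact tests with Benjamini-Hochberg adjustment, 1025 of 10904 8-mers tested were enriched at X summits and 841 depleted, and at autosomal summits 1060 of 16050 were enriched and 768 depleted. Of the 9412 tested in both, 480 were enriched in both, where independent lists would share 66.3. These lists are not independent, since 8-mers overlap and both sets of summits were richer in GC than the windows beside them. On autosomes the GC was 48.7% against 36.7%, and the X values are given below. The shared number was not recomputed with matched GC, so it does not separate shared sequence from shared composition. Set directly against autosomal windows, X windows had 2 of 8233 8-mers at a higher share and 0 at a lower share, CGCAGGGA (20 of 563 against 0 of 780, exact test, adjusted p = 3.79e-04) and CCCTGCGC (25 against 4, adjusted p = 0.00707), and both lie in the MEX consensus or its complement. Windows at X summits had 48.9% GC and those 2000 bp away 35.3%. Against X windows matched on GC, 400 of 12934 8-mers were enriched, led again by AGACGCAG (69 of 563 against 14 of 1126, exact test, adjusted p = 2.85e-17). Within 50 bp of the summit 369 of 3356 were enriched.

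Among 20 gene lists fixed before the data were examined, ribosomal protein genes stood out. An IDR summit lay within 1000 bp of a 5′ end of 21 of 79 cytosolic ribosomal protein genes, 7.01 times the 2.997 expected from genes of the same chromosome class (two-sided exact p from stratified hypergeometric distributions, adjusted p = 3.39e-11 over 20 lists), among them rpl-3 (signal 265), rpl-15 (233), rpl-35 (183) and rpl-11.2 (151). Heat shock and DnaJ genes had 11 of 51 (2.22 expected, exact test, adjusted p = 7.80e-05), with the chaperone genes hsp-3 (246), dnj-14 (184), hsp-60 (159) and hsp-90 (135). Histone genes had 9 of 72 (2.90 expected, exact test, adjusted p = 0.0148), where neighbouring genes such as his-67 and his-68 (230) or his-59 and his-60 (121) share a summit. Against all small RNA genes, tRNA genes had 209 of 612 (160 expected, exact test, adjusted p = 4.17e-10), 118 of 276 on X and 91 of 336 on autosomes, while miRNA genes had 28 of 261 (62.1 expected, adjusted p = 3.34e-08), snRNA genes 13 of 129 (25.8 expected, adjusted p = 0.00858) and snoRNA genes 75 of 346 (72.8 expected, adjusted p = 0.982). The tRNA genes fill this background, so these lists were also set against others, chosen after the result was seen. Without tRNA genes in the background, 38.9 miRNA and 20.3 snRNA genes were expected and neither list passed (exact test, adjusted p = 0.0598 and 0.121), while snoRNA genes exceeded 53.6 (adjusted p = 9.96e-05). Against protein-coding genes all 4 lists lay above the expected number, miRNA genes 1.85 times, snRNA genes 2.63 times, tRNA genes 3.99 times and snoRNA genes 4.68 times (exact test, adjusted p = 0.00878, 0.00878, 3.18e-80 and 4.79e-29).

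Genes of sex determination and X counting had 4 of 18 with a summit (0.951 expected) and did not pass (exact test, adjusted p = 0.0603). They were ceh-39 (signal 441, with a MEX match of 2 mismatches), xol-1 (216) and sex-1 (99.1), all on X, and sea-2 (96.5) on chromosome II. ceh-39 and sex-1 are X signal elements that repress xol-1. Of 10 genes of the dosage compensation complex, dpy-27 (141) and sdc-1 (102) had one (0.511 expected, exact test, adjusted p = 0.292). Cell cycle and DNA replication genes had 6 of 48 (exact test, adjusted p = 0.0598), among them cye-1 (258) and cdk-4 (226), and body wall muscle genes 4 of 18 (adjusted p = 0.111), among them unc-112 (140) and act-4 (104). Collagens had 12 of 156 (adjusted p = 0.292), led by col-185 (476), nuclear hormone receptors 12 of 269 (adjusted p = 1), led by nhr-255 (519), epidermal genes 3 of 16 (adjusted p = 0.209), vacuolar ATPase genes 2 of 20 (adjusted p = 0.697), ceh homeobox genes 1 of 63 (adjusted p = 0.345) and germline genes 1 of 21 (adjusted p = 1), by the same exact test. Genes of the pharynx (11), intestine (16) and neurons (22) had 0, where 0.472, 0.803 and 1.02 were expected (adjusted p = 1, 1 and 0.931 by that exact test).

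Neighbouring IDR summits on X lay closer together than equal numbers of X summits drawn from the pooled list, with a median distance of 17312 bp against 20285 bp (95% of draws 18431 to 22303 bp, two-sided permutation p = 0.00300 from 10000 draws). The 50 strongest X summits had a median distance of 188031 bp against 238125 bp drawn and did not pass (permutation p = 0.153). They ran from position 410149 to position 17545733, and their widest gap, 1417008 bp, began at position 8048854. From the left to the right end of X, its 5 equal parts held 123, 107, 91, 125 and 117 IDR peaks, and 16, 4, 4, 14 and 12 of the 50 strongest.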

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

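Of the tests in this part, those on the background of the peak caller, on the number of peaks that the transgene region can hold, on MEX-like sequence with 3 mismatches and on GC outside the 50 strongest X peaks were chosen only after the result was seen. Peaks on the mitochondrial genome, which no comparison uses, numbered 16 in the list of replicate 2 and 0 in that of replicate 1, above the 3 that a count of 0 allows, and the IDR list held 1 mitochondrial peak with a signal of 885.

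The X excess did not end with the strongest peaks: at ranks below 200, X held 36.2% of 1143 IDR peaks. Shoulders of the strongest X sites were tested by leaving out 23 peaks within 10000 bp of the 50 strongest X summits, after which X still held 34.9% (interval 32.1 to 37.8%), above its 17.7% of the sequence. A background raised on X alike at all signal levels falls short, as X held 20.4% of the rest of the pooled list. The odds ratio against it was 2.22 (interval 1.96 to 2.52). This restates the fall of the X share with rank that had already been seen, so it is no separate support. A background that grows with signal was not tested. Extra copies of the transgene could place peaks at sdc-2 alone, and 0 IDR peaks lay within 20000 bp of it. The excess of 212 (interval 180 to 245) therefore lay elsewhere, so peaks called in this region were not its source. Peaks were called against a control alignment that was not analysed here, so the 0 does not show whether extra copies are present. The region was sparse in called peaks, with 1 in the pooled list. By the later rule, 113 peaks of median width fit end to end there, fewer than this excess. Outside the 50 strongest, X IDR summits lay near protein-coding gene starts more often than pooled X peaks below the IDR threshold. Whether a promoter signal has a part in the X excess was not tested. With 1 group, no biological explanation was tested, and an X excess from binding of SDC-2 beyond the strongest sites remains a hypothesis.

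The 780 autosomal IDR peaks were weighed against MEX and a general promoter signal. MEX with at most 2 mismatches was more frequent than beside them, but its share of 1.15% has an upper bound of 2.18%, so matches this close could account for few of these peaks. With at most 3 mismatches the share was 16.7% (interval 14.1 to 19.5%), above the 4.04% beside them. It was also above the highest share of 12.6% in 100 draws of autosomal windows matched on GC. The bound at 2 mismatches therefore does not settle this, and MEX-like sequence may have a part in some of these peaks. The draws matched GC only. AGACGCAG, at 12.3% of X and 12.2% of autosomal summits, shares CGCAG with MEX, and its part in this share was not separated. A general promoter signal is consistent with 62.1% of autosomal IDR summits (interval 58.5 to 65.5%) lying within 1000 bp of a protein-coding 5′ end, against 46.3% of the other autosomal peaks of the pooled list. X IDR peaks outside the 50 strongest shared this shift. Of these, 56.3% lay that close, against 38.7% of pooled X peaks below the IDR threshold (Fisher exact test, adjusted p = 7.58e-14). Nearness to promoters was therefore not particular to the autosomal peaks. Whether this nearness reflects SDC-2 at promoters or chromatin that is pulled down with any antibody stays open. ChIP of an untagged strain was not analysed here, and no biological explanation was tested.

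The MEX share of X IDR peaks could come from their GC content, since windows at X summits had 48.9% GC and random X windows 35.1%. In 100 draws of X windows matched on GC the share had a median of 1.07% and reached at most 2.31%, below the lower bound of 4.22% around the observed 6.04%. GC content alone therefore falls short of the share over all X IDR peaks, which rests on the 50 strongest, with 22 of the 34 matches. For the other 513, with 12 matches (2.34%, interval 1.21 to 4.05%), matched draws had a median of 1.17% and reached 2.73%. GC and a preference for MEX cannot be told apart over these 513 as a whole. The matches were uneven, at 6 of 50 at X ranks 51 to 100 (12%, interval 4.53 to 24.3%), 3 of 100 at ranks 101 to 200 and 3 of 363 below. Draws were not made for these parts, and no biological explanation was tested.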

How the results depend on the processing

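The alternatives with backgrounds matched on GC, with other backgrounds for small RNA genes, with other numbers of strongest X peaks, without the 50 strongest X peaks and, for MEX sequences over the genome, with single replicates were chosen after seeing the data. Of 224 results recomputed under an alternative, 198 kept their direction and their side of the threshold, and 13 reversed. Values and counts with no test were counted as kept within the interval, within 1.5 times or within the same part of the list. The 198 include settings that could not change the result, named below. They also include named peaks that only had to stay among the 1343 strongest, and gene lists that passed in neither setting. The tally is therefore no measure of stability. Replicate agreement, 61.7% with summits within 100 bp, was 67.8% with an overlap of at least 1 bp, 71.1% among the 671 strongest peaks of each replicate and 52.3% among the 2686 strongest, in place of 1343. The X minus autosome difference in MEX share, 4.89 percentage points, was 2.87 with at most 3 mismatches and no longer passed. The 8-mers enriched at X summits, 1025 of 10904 tested, were 2 of 8233 against autosomal peak windows and 400 of 12934 against X windows matched on GC. Within 50 bp they were 369 of 3356, so this lower count goes with fewer 8-mers tested. Here windows are shorter or the background shares the composition of peaks, and otherwise the cause was not tested. Among the gene lists, collagens passed without replicate 2 (exact test, adjusted p = 0.0470) and body wall muscle at 500 bp (adjusted p = 0.0478). Among lists that did not pass, leaving out replicate 2 moved body wall muscle from 4 genes to 2 (3.40 to 1.74 times), ceh homeobox genes from 1 to 3 (0.275 to 0.843) and germline genes from 1 to 2 (1.32 to 2.65), and leaving out replicate 1 moved ceh homeobox genes to 2 (0.568). Genes of sex determination and X counting went from 4 to 3 without replicate 2 (4.21 to 3.21 times, exact test, adjusted p = 0.275). Cell cycle and DNA replication genes went from 6 to 4 (3.19 to 2.14 times, exact test, adjusted p = 0.419). Without replicate 1 these 2 lists kept their counts and did not pass. The reversals were in 8 gene lists. Those of small RNA genes depend on the background: miRNA genes, 0.451 times the expected number, had 1.85 times and snRNA genes, 0.504, had 2.63 against protein-coding genes, and 0.719 and 0.641 without tRNA genes in the background, no longer passing. The snoRNA genes passed at 1.40 without tRNA genes and at 4.68 against protein-coding genes. The other reversals passed in neither of the settings compared (lowest adjusted p 0.292 and 0.615, exact tests). Collagens, 1.57 times the expected number, had 0.545 times at 500 bp. Nuclear hormone receptors, 1.05, had 0.737 at 500 bp, 0.766 at 2000 bp, 0.795 without replicate 2 (1.08 without replicate 1) and 0.790 among autosomal genes. The snoRNA genes, 1.03, had 0.980 at 500 bp and 0.993 without replicate 1 (1.07 without replicate 2), and germline genes, 1.32, had 0 at 500 bp and 0.887 at 2000 bp. Without replicate 1, pharynx genes went from 0 to 2.19 and neuron genes from 0 to 1.01. The X share of IDR peaks was 41.3 to 42.0% in the single replicates and 53.7% in the upper part of the list by signal. Taking the top of the pooled list gives the IDR list itself, and leaving out the regions of sdc-2 and unc-119 removed no peak, so these settings say nothing about stability. The unknown depth limits what can be said of weak peaks such as those at her-1.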

Other observations

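Of the tests in this part, the comparison of tRNA with protein-coding genes and that of strong sites along X were chosen only after the result was seen. tRNA genes had IDR summits more often than protein-coding genes on both kinds of chromosome. On X, 118 of 276 tRNA genes (42.8%) and 305 of 2731 protein-coding genes (11.2%) had a summit within 1000 bp (Fisher exact odds ratio 5.94, p = 2.22e-35), and on autosomes 91 of 336 (27.1%) and 621 of 17242 (3.60%; odds ratio 9.94, p = 7.34e-50). Seen from the peaks, 102 of 563 X summits (18.1%) and 79 of 780 autosomal summits (10.1%) lay that close to a tRNA 5′ end, against 3.05% and 1.32% of the other X and autosomal peaks of the pooled list. The 50 strongest X peaks did not stand apart here, with 10 near a tRNA gene (20%) against 17.9% of the other X peaks (Fisher exact p = 0.702). Clusters of tRNA genes that share a summit could inflate the count, but with genes under 2000 bp apart merged, 90 of 183 X clusters (49.2%, interval 41.7 to 56.7%) had a summit, against 11.998% of X protein-coding clusters. A hypothesis from these counts is that tRNA genes may draw the tagged protein or the pull-down itself, which these lists do not separate.

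Strong sites may be fewer in the left middle of X. Of the 50 strongest X summits, 8 lay in the second and the third of its 5 equal parts, against 190 of the other 513 (37.0%; Fisher exact odds ratio 0.324, p = 0.00286). The parts were picked after their counts were seen, so this is a hypothesis.

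Weaker X peaks were tested for nearness to the strong ones, as a spread of the protein from strong sites could give. The other 513 X IDR summits lay a median of 117394 bp from the nearest of the 50 strongest, against 141437 bp in draws from the rest of the pooled list (95% of draws 125560 to 157003 bp, permutation p = 0.00220). Without summits within 10000 bp of a strong one, in the peaks and in the draws, the median was 145270 bp for 469 summits against 153592 bp (95% of draws 136560 to 169842 bp, permutation p = 0.327). The nearness therefore rests on summits within 10000 bp, where shoulders of strong peaks are a candidate explanation that these lists do not separate from binding.

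The region of sdc-2 with 20000 bp to either side (X:11502707-11553450) held 1 peak of the pooled list, 3 of replicate 1 and 0 of replicate 2, where other X windows of this size held a median of 16. As few were found in 6 of 1757 such windows (0.341%). The same region of unc-119 on chromosome III held 20, with a median of 13 in other windows.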
